A study of Mus musculus with 6 samples.

How the data were processed

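Total RNA of CD4+CD62L- T cells, sorted by flow cytometry from mouse lymph nodes, was measured on 1-colour Affymetrix MoGene 1.0 ST arrays after amplification and biotin labelling, per the labels' protocols. The 6 arrays fall into 2 genotypes of 3 mice-derived samples each, which the series' design text calls biological replicates. Dicer WT samples came from animals with floxed Dicer and no Cre. Dicer KO samples came from animals with floxed Dicer and Cre driven by the Cd4 promoter. No treatment was given, per the labels. Each sample's genotype was taken from its label.

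The values used are log values that the authors deposited as 1 table of 28815 array rows by 6 arrays, read here as log2. The submitters' processing notes name MAS5, with no version and no role. The scale, centring and normalization steps are not given in the sources used here. The values showed that every row had been centred on the median of its 6 arrays (largest absolute row median 5e-07), so the table holds differences between arrays and no expression levels. Values ran from -2.59 to 3.00 with 0 missing. Array medians over all rows were 0.0014, 0.0063 and 0.0024 for Dicer WT 1 to 3 and -0.0037, -0.0088 and 0.0022 for Dicer KO 1 to 3. Centring a row cancels in the difference between genotypes. The log base is not stated. The binary step of the stored numbers, which grows with the size of the number before centring, placed 16.4% of rows at a level of 8 or more and 80.5% at 4 to 8 on the log scale, and 3.07% gave a finer step or none. Levels that high rule out base 10, but a natural log is not fully excluded, and every fold printed here assumes base 2. The step also served as a coarse level class: 94.0% of 216 rows of ribosomal protein genes but 1.55% of 1035 rows of olfactory receptor genes were in the higher class. A row's class can be wrong. The higher class needs the coarse step on all 6 arrays, so a gene at that level in 1 genotype only can fall in the lower class. The class is thus not independent of the genotype difference. Iigp1, the largest rise, was in the lower class.

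Rows were named through GEO's platform annotation. Of the rows, 21780 had 1 gene symbol, 1605 had several and 5430 were unnamed here. Of the rows with 1 symbol, 21689 matched the RefSeq gene table of assembly GRCm38.p6 by gene ID and took its symbol, and 91 kept the annotation's symbol. Rows with several symbols or none were left out of the gene-level tests, so Lck and Tcf7 have no value here. The rows gave 19935 genes, of which 998 lay on several rows and were averaged. No coordinates are printed, because the files name no genome build.

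Differences between Dicer KO and Dicer WT were tested per gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on 3 against 3 arrays), with Benjamini-Hochberg adjustment over all genes and a threshold of adjusted p 0.05. Every adjusted p of a single gene below is from this test, and each difference is given with the SE of the moderated fit. The test design, the gene lists and the rule for named genes were written before the data were examined. The design had assumed levels: a filter at the 30th percentile of the mean, the brightest row standing for a gene, and quantile normalization, a 50th percentile filter, another pseudocount and a trended variance prior as alternatives. The centring removed the levels these need, so no filter was applied, the mean of a gene's rows was used, and those alternatives were not run. A planned test of seed sites of microRNAs in untranslated regions needs sequences and was not analysed here.

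The 35 fixed gene lists cover microRNA biology, T cell states and signalling, cell cycle, death and stress programmes, metabolism, ribosomal proteins, and markers of other cells that a lymph node sort could hold. Each list was tested with limma's camera at the preset correlation of 0.01 with Benjamini-Hochberg adjustment over the lists, beside camera with an estimated correlation and fry. Members past the threshold were counted after adjustment over all genes and after adjustment over the list alone. A further 8 lists were written after the data had been looked at. Named genes are Dicer1; the 12 largest rises and 12 largest falls among genes past the threshold whose arrays do not overlap between genotypes, leaving out microRNA precursors, antigen receptor segments and unnamed gene models; for each list up to 5 members past the threshold by lowest p, or up to 3 by lowest p where none passed; and the sort markers Cd4, Cd8a and Cd44. A gene named outside this rule is marked as chosen after its values were seen.

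The procedure was tested on simulated data for the comparison of Dicer KO with Dicer WT, using the real residual spread of the 19935 genes and 200 changed genes. It recovered 73.1% of genes changed by a log2 difference of 0.5, 91.0% of those changed by 1 and 100% of those changed by 2, with 0 wrong signs and 13 unchanged genes called. A list of raised genes was called and 0 of 40 unchanged lists were. Simulated genes were independent of each other, unlike real ones. For arrays, the number of replicates limits the precision. The alternatives run were another centring of each array, array weights, the replicate number as a block, each array left out, a minimum log2 difference of 1 and all rows of the table. Alternatives chosen after seeing the data were genes of the higher level class, centring within level classes, a robust variance prior, the first row of each gene, and leaving out both arrays with low B cell markers.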

Results

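The transcriptomes of CD4+CD62L- lymph node T cells were compared between 3 Dicer WT and 3 Dicer KO samples. Dicer is the RNase that cuts microRNA precursors into mature microRNAs, and in the Dicer KO animals the floxed gene is deleted by Cre expressed from the Cd4 promoter during T cell development. The comparison asks which transcripts differ between CD4 T cells of these genotypes. Each value is a deposited log2 value centred on the median of its row over the 6 arrays, so differences between genotypes are given and levels are not. In a principal component analysis of 19935 genes, the component with 55.4% of the variance separated the genotypes, and the next one, with 21.2%, set Dicer WT 3 at -14.1 and Dicer KO 3 at -10.5 apart from Dicer WT 1, Dicer WT 2 and Dicer KO 1, at 8.05, 8.22 and 10.2.

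The row of Dicer1 did not differ between genotypes, with a log2 difference of Dicer KO minus Dicer WT of 0.02 ± 0.09 (SE, n = 3 per genotype, limma adjusted p = 0.949). The Dicer WT arrays read 0.12, 0.02 and -0.10 and the Dicer KO arrays 0.21, -0.02 and -0.09. Which exons the row's probes cover is not given in the sources used here, and probes outside the deleted exons would read the remaining transcript. The row therefore checks nothing about the deletion, and the genotypes rest on the labels.

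Dicer KO cells had higher transcript levels of interferon-inducible genes, 7 of 24 histone genes and the terminal transferase Dntt, and lower levels of ribosomal protein genes. With a correlation between genes estimated from the data, the interferon, histone and ribosomal lists were not called (adjusted p 0.189, 0.144 and 0.179). Of 19935 genes, 1741 passed the threshold, 1184 higher and 557 lower in Dicer KO, and the arrays of the 2 genotypes did not overlap for any of them. Over all genes, 26.2% had arrays that did not overlap, where chance gives 10%. A log2 difference of at least 1 was reached by 93 of the higher and 10 of the lower genes. The count fell to 849 without Dicer WT 1, to 1050 without Dicer WT 2 and to 729 without Dicer KO 2, and that of lower genes to 366 without Dicer KO 1, while 646 genes were called with every array and with any 1 left out. Genes of the higher level class leaned upward, with a median difference of 0.12 against -0.019 for the others, and supplied 654 of the higher and 133 of the lower calls.

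The largest rise was that of Iigp1, an interferon-inducible GTPase, 8.61-fold higher in Dicer KO (log2 3.11 ± 0.21 SE, adjusted p = 0.000799). Dntt, which adds nucleotides at V(D)J junctions in developing lymphocytes, was 5.81-fold higher (2.54 ± 0.20, adjusted p = 0.00107). The histone genes H2bc4 and H2bc8 were 6.29-fold and 4.30-fold higher. Of the other 8 largest rises, Oasl2 (5.40-fold), Parp12 (4.04-fold), Gbp3 (3.34-fold) and Ifitm3 (3.26-fold) are interferon-inducible, D17H6S56E-5 rose 5.41-fold and the coronin family member Coro2a 4.11-fold. Mtmr9 was 3.96-fold higher, and its call was lost without Dicer KO 2 (adjusted p = 0.0506). The vomeronasal receptor gene Vmn2r96 was 3.36-fold higher (adjusted p = 0.0423), and its call was lost without any 1 of the WT arrays or Dicer KO 2 (adjusted p 0.0861 to 0.117).

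**Figure D1:**
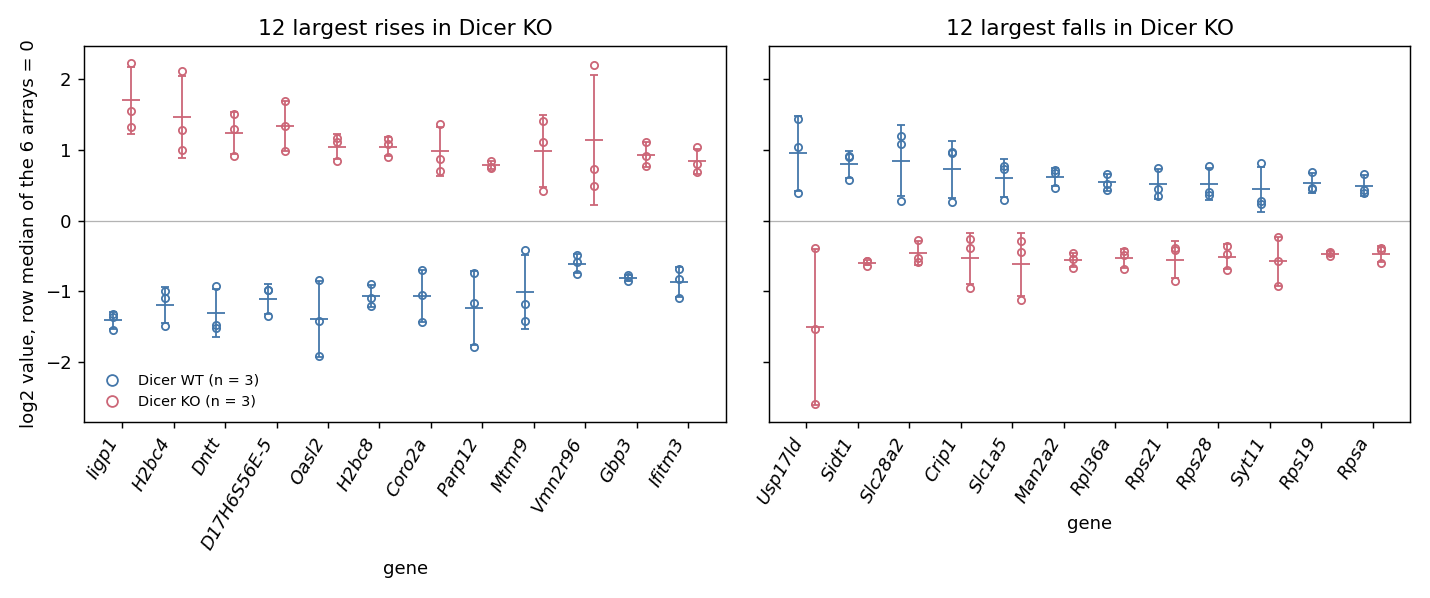
Log2 values of the 12 largest rises (left) and 12 largest falls (right) on each array, with the row median of the 6 arrays at 0; circles are arrays, and bars give the mean and SD of 3 Dicer WT (blue) and 3 Dicer KO (red) arrays. The 24 genes were picked among those whose genotypes do not overlap. Differences ran from 3.11 for Iigp1 to 1.71 for Ifitm3 among the rises. Among the falls they ran from -2.45 for Usp17ld to -0.96 for Rpsa, and Usp17ld has the widest spread among Dicer KO arrays.

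Among the falls, Sidt1, a transmembrane protein of the SID1 family, changed by -1.39 ± 0.10 on the log2 scale (adjusted p = 0.000799) and the Golgi mannosidase Man2a2 by -1.17 ± 0.08 (adjusted p = 0.000904). Ribosomal protein genes made up 5 of the 12, namely Rpl36a (-1.07), Rps21 (-1.06), Rps28 (-1.03), Rpsa (-0.96) and Rps19, whose difference lay between these last. The 5 remaining falls were called with all 6 arrays and not with every 5 of them. Usp17ld (-2.45 ± 0.53, adjusted p = 0.0335) lost its call without any 1 of the WT arrays or Dicer KO 2 (adjusted p 0.0599 to 0.119). The nucleoside transporter Slc28a2 (-1.31) lost it without Dicer WT 1, Dicer KO 1 or Dicer KO 2 (0.0503 to 0.0691), Crip1 (-1.26) without Dicer WT 1, Dicer WT 2 or Dicer KO 2 (0.0504 to 0.0821), the glutamine transporter Slc1a5 (-1.22) without Dicer WT 1 or Dicer WT 2 (0.0754 to 0.0808), and Syt11 (-1.01) without Dicer WT 1, Dicer WT 2, Dicer KO 1 or Dicer KO 2 (0.0622 to 0.104).

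Interferon-stimulated genes were higher in Dicer KO as a group. Of 33 measured members, 18 rose and 0 fell (27 and 0 adjusted over the list alone), all 33 had a positive difference, and the list median was 0.77, or 1.71-fold (camera adjusted p = 4.78e-20; adjusted p = 0.189 with an estimated correlation). Examples are the nucleic acid sensor Zbp1 (1.43 ± 0.10), the ADP-ribosyltransferase Parp14 (1.29 ± 0.11) and the transcription factor Irf1 (0.77 ± 0.07). The list medians were -0.42, -0.74 and -0.26 on Dicer WT 1 to 3 and 0.53, 0.32 and 0.18 on Dicer KO 1 to 3. The median of 18 B cell genes was -0.51, 0.02 and -0.24 on the same WT arrays and 0.08, 0.04 and 0.09 on the KO arrays. Without Dicer WT 1 and Dicer WT 3, the arrays of low B cell markers, the interferon list median was 0.94. That fit leaves Dicer WT 2, the WT array with the lowest interferon median, as the lone WT array. The members higher numbered 10 without Dicer WT 1 and 9 without Dicer KO 2.

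Ribosomal protein genes were lower in Dicer KO. Of 61 members, 50 fell and 0 rose (56 and 0 adjusted over the list alone), with a median of -0.54, or 1.45-fold higher in Dicer WT (camera adjusted p = 3.84e-36; adjusted p = 0.179 with an estimated correlation). Rps21 (-1.06 ± 0.15) and Rps29 (-0.81 ± 0.09) are components of the small subunit. Rows of ribosomal protein genes can also bind transcripts of processed pseudogenes, so single members are uncertain. Without Dicer WT 1 and Dicer WT 3, the median was -0.47 and 4 members were called.

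Replication-dependent histone genes, which are normally expressed in S phase, were higher in Dicer KO. Of 24 members, 7 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 0.38 (camera adjusted p = 2.92e-08; adjusted p = 0.144 with an estimated correlation). H4c9 rose by 0.98 ± 0.14, and the members called numbered 4 without Dicer WT 1 and 3 without Dicer KO 2, while the median was 0.25 without Dicer KO 3. Cell cycle genes had a median of 0.29 over 39 members and passed camera (adjusted p = 1.25e-06; adjusted p = 0.568 with an estimated correlation), yet only Pcna, the polymerase clamp, passed by itself (0.37 ± 0.08, adjusted p = 0.0334; 0 members adjusted over the list alone). The call of Pcna held only without Dicer KO 1 among the fits that left out 1 array (adjusted p 0.0575 to 0.105 in the others). The cell cycle medians were -0.10, 0.01 and -0.13 on Dicer WT 1 to 3 and -0.01, 0.11 and 0.48 on Dicer KO 1 to 3. Without Dicer KO 3 the median difference was 0.15 and the list was still called (adjusted p = 0.000457), without Dicer KO 1 there were 5 members called, and fry did not call the list (adjusted p = 0.324).

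Of 24 genes of microRNA biogenesis and silencing, 4 rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 0.16 (camera adjusted p = 6.95e-05; adjusted p = 0.153 with an estimated correlation). The RNA helicase Mov10 was 2.24-fold higher (1.16 ± 0.05), the Argonaute protein Ago2, which binds mature microRNAs, 1.84-fold (0.88 ± 0.05) and the nuclear processing enzyme Drosha 1.35-fold (0.43 ± 0.06). The list of 61 targets of T cell microRNAs from single-gene studies had 13 members higher and 1 lower (18 and 2 adjusted over the list alone) and a median of 0.19 (camera adjusted p = 4.25e-08; adjusted p = 0.144 with an estimated correlation). Higher members included the survival factor Mcl1 (0.74 ± 0.06), the TGF-beta receptors Tgfbr1 (1.17 ± 0.11) and Tgfbr2 (0.67 ± 0.06), the Th2 factor Gata3 (0.71 ± 0.06) and the cyclin Ccnd2 (0.93 ± 0.08). The lower member was Irak1 (-0.31 ± 0.06), named after its value was seen and not called without Dicer WT 2, Dicer KO 1 or Dicer KO 2 (adjusted p 0.0566 to 0.0783). Of 300 microRNA precursor genes, 6 fell and 0 rose (1 and 0 adjusted over the list alone), with a median of -0.029. The camera adjusted p was 0.015, or 0.283 with an estimated correlation. Mir128-2 changed by -0.47 ± 0.06. The precursor list lost its call when arrays were centred within level classes (adjusted p = 0.0641), and its lower members numbered 3 without Dicer WT 1 and 1 without Dicer KO 2. Among 20 microRNA host transcripts, Nfyc rose by 0.34 ± 0.06 and 0 fell, with the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.354). The call of Nfyc was lost without Dicer WT 1, Dicer KO 2 or Dicer KO 3 (adjusted p 0.0576 to 0.0899).

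Genes of naive and quiescent T cells were higher in Dicer KO. Of 22 members, 9 rose and 0 fell (12 and 1 adjusted over the list alone), with a median of 0.37 (camera adjusted p = 2.77e-08; adjusted p = 0.231 with an estimated correlation). The members higher numbered 5 without Dicer WT 1 and 5 without Dicer KO 2. Igfbp4 (1.01 ± 0.07), the lymph node homing receptor Ccr7 (0.64 ± 0.07) and the antiproliferative genes Btg1 (0.63 ± 0.09) and Btg2 (0.69 ± 0.06) were among them. Of the sort markers, Cd4 was higher (0.67 ± 0.07, adjusted p = 0.00328), while Cd8a (-0.09 ± 0.18, adjusted p = 0.857) and Cd44 (0.28 ± 0.14, adjusted p = 0.304) did not pass. Of 28 T cell receptor signalling genes, 6 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 1.11e-05; adjusted p = 0.189 with an estimated correlation). Ubash3a (0.54 ± 0.06), Grap2 (0.69 ± 0.09) and Rasgrp1 (0.80 ± 0.10) rose and the inhibitory coreceptor Cd5 changed by -0.44 ± 0.06. This list was not called among genes of the higher level class alone (adjusted p = 0.403), to which 27 of its members belong.

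Some TGF-beta pathway genes were higher in Dicer KO. So were some PI3K and mTOR pathway genes. Of 19 TGF-beta pathway genes, 5 rose and 0 fell (8 and 1 adjusted over the list alone): Tgfbr1, Tgfbr2, Tgfbr3 (1.07 ± 0.09), the ubiquitin ligase Smurf2 (0.87 ± 0.09) and Smad3 (0.69 ± 0.13). The list median was 0.09 (camera adjusted p = 0.0017; adjusted p = 0.144 with an estimated correlation), and 0.14 without Dicer WT 2 or without Dicer KO 3. The call of Smad3 was lost without Dicer WT 1, Dicer WT 2, Dicer KO 1 or Dicer KO 2 (adjusted p 0.0658 to 0.0945). Of 27 PI3K and mTOR pathway genes, 8 rose and 0 fell (10 and 1 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 6.98e-05; adjusted p = 0.153 with an estimated correlation). The kinase subunits Pik3cd (0.73 ± 0.06) and Pik3r1 (0.56 ± 0.06), the PI3K inhibitor Pik3ip1 (0.88 ± 0.09) and the kinase Sgk1 (1.05 ± 0.12) were examples, and the members higher numbered 5 without Dicer WT 2 and 4 without Dicer KO 2. Neither list was called among genes of the higher level class alone (adjusted p = 0.536 and 0.31).

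Among 26 apoptosis regulators, members that block and members that drive cell death were higher in Dicer KO: 10 rose and 0 fell (13 and 2 adjusted over the list alone), with a median of 0.34 (camera adjusted p = 8.83e-06; adjusted p = 0.144 with an estimated correlation). They included the antiapoptotic genes Mcl1 and Cflar (0.47 ± 0.05), and the proapoptotic genes Fas (0.67 ± 0.10), Casp6 (0.46 ± 0.06) and Bcl2l11 (0.49 ± 0.08), the last not called without Dicer WT 1 (adjusted p = 0.054) or Dicer KO 2 (0.06). In all, 5 members rose without Dicer WT 1 and 4 without Dicer KO 2. Of 25 p53 target genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.04 (camera adjusted p = 0.0119; adjusted p = 0.153 with an estimated correlation). The median was 0.09 without Dicer WT 3, 0.02 without Dicer KO 2 and 0.08 without Dicer KO 3. The members that moved have other roles too: Ccng1 (0.70 ± 0.06) and Trp53inp1 (1.01 ± 0.12) are p53-responsive, Tap1 (0.82 ± 0.08) is the peptide transporter of antigen presentation, Btg2 is also on the naive list, and the kinase gene Plk3 changed by -0.66 ± 0.09.

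Of 18 Th1 genes, 7 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 0.21 (camera adjusted p = 6.98e-05; adjusted p = 0.144 with an estimated correlation). They included receptor chains and transcription factors, such as Il12rb1 (0.37 ± 0.06), Ifngr2 (0.44 ± 0.08), Stat4 (0.68 ± 0.12) and Runx3 (0.37 ± 0.07). Of the list, 1 member was called without Dicer WT 1 and 1 without Dicer KO 2. Except for Il12rb1, the genes named lost their calls without Dicer WT 1 or Dicer KO 2 (adjusted p 0.0611 to 0.0736), and Ifngr2 also without Dicer WT 2 (0.0545). Regulatory T cell genes had 3 of 23 members higher and 0 lower (also 3 and 0 adjusted over the list alone), with a median of 0.09 (camera adjusted p = 0.0162; adjusted p = 0.166 with an estimated correlation), and the call was lost without Dicer WT 3 (adjusted p = 0.092) and without both Dicer WT 1 and Dicer WT 3 (0.174, with 0 members called). Those members were Capg (0.76 ± 0.11), Tnfrsf9 (0.40 ± 0.07) and Gpr83 (0.92 ± 0.22). Tnfrsf9 lost its call without Dicer WT 1, Dicer KO 2 or Dicer KO 3 (0.0522 to 0.0849) and Gpr83 without any array but Dicer KO 1 (0.0592 to 0.167), which left 1 member called without Dicer WT 1, Dicer KO 2 or Dicer KO 3. Oxidative phosphorylation genes had 4 of 81 members higher, among them Atp5b (0.56 ± 0.06) and Sdha (0.48 ± 0.05), and 6 lower, among them Atp5mpl (-0.75 ± 0.09), with the same counts adjusted over the list alone. Their median was -0.09 (camera adjusted p = 0.0119; adjusted p = 0.758 with an estimated correlation), and the call was lost with fry (0.462), with array weights (0.057) and without Dicer WT 3 (median -0.04, adjusted p 0.141) or Dicer KO 1 (median -0.04, 0.339), and without both Dicer WT 1 and Dicer WT 3 (median -0.05, 0.226, with 0 members called). The members higher and lower numbered 2 and 3 without Dicer WT 1 and 2 and 1 without Dicer KO 2.

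**Figure D2:**
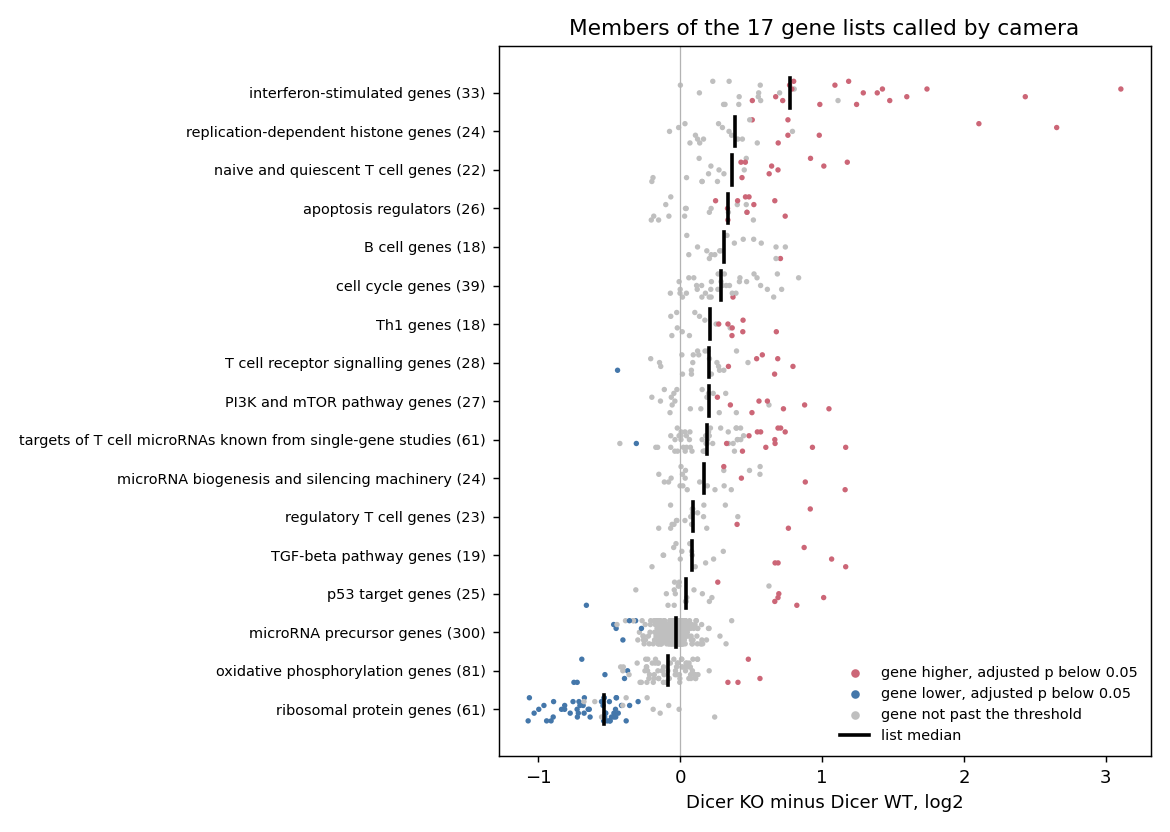
Log2 difference of Dicer KO minus Dicer WT (x axis) for each member of the 17 gene lists called by camera, with the number of genes tested in parentheses; coloured points passed adjusted p 0.05, grey points did not, and black bars are list medians. Medians ran from -0.54 for ribosomal protein genes to 0.77 for interferon-stimulated genes.

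Camera called 17 of the 35 lists, 14 higher and 3 lower, and 0 of them with an estimated correlation, where the smallest adjusted p was 0.144. The remaining call was that of 18 B cell genes, with a median of 0.31 (adjusted p = 1.88e-05; adjusted p = 0.464 with an estimated correlation), of which Bank1 alone passed by itself (0.71 ± 0.11), also adjusted over the list alone, but not without Dicer KO 2 (adjusted p = 0.0515). The median was 0.19 without Dicer WT 1, 6 members were called without Dicer WT 2, and fry did not call the list (adjusted p = 0.178). The B cell median difference was 0.03 without Dicer WT 1 and Dicer WT 3. These arrays were left out because their B cell markers were low, which left Dicer WT 2 as the lone WT array.

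The other 18 lists were not called. Activation and effector memory genes had 3 of 40 members higher, such as Cd69 (0.63 ± 0.11), and 4 lower, such as Id2 (-0.82 ± 0.15) and Nr4a1 (-0.60 ± 0.10; adjusted p of the list 0.664). Immediate early and dissociation stress genes had 3 of 33 higher, with Nfkbia at 0.59 ± 0.05, and 2 lower, with Egr1 at -0.49 ± 0.06 (adjusted p = 0.664). Th2 genes had 3 of 16 higher, among them Il4ra (0.73 ± 0.08; adjusted p = 0.123), and the list was called without Dicer KO 1 (adjusted p = 0.0318, median 0.07), while its median was -0.01 without Dicer KO 3. Th17 genes had 1 of 17 higher, Tmem176b (1.01 ± 0.14), and 1 lower, Aqp3 (-0.40 ± 0.08; adjusted p = 0.799). Follicular helper genes had 2 of 17 higher, Bcl6 (0.57 ± 0.09) and Il6ra (0.43 ± 0.08; adjusted p = 0.777). Cytotoxic and CD8 T cell genes had 2 of 23 higher, with the granzyme inhibitor Serpinb9 at 1.56 ± 0.10 (adjusted p = 0.203; 0.0452 with fry). Glycolysis genes had 3 of 18 higher, with Hif1a at 0.45 ± 0.05, and 2 lower, with Tpi1 at -0.81 ± 0.14 (adjusted p = 0.546). Adjusted over the list alone, the counts higher and lower were 4 and 0 for Th2, 5 and 1 for cytotoxic and 5 and 3 for glycolysis genes, and did not change for the activation, immediate early, Th17 and follicular helper genes. Of the genes named from these 7 lists, Cd69, Bcl6, Id2, Nr4a1, Il6ra, Tpi1 and Aqp3 lost their calls without Dicer KO 2 (adjusted p 0.055 to 0.0952). Some of them also lost it without Dicer WT 1 (Id2, Il6ra and Tpi1, 0.0582 to 0.0786), Dicer WT 2 (Id2, Nr4a1, Il6ra and Aqp3, 0.0508 to 0.0774) or Dicer KO 3 (Aqp3, 0.062). Without Dicer WT 1 the counts higher and lower were 1 and 1 for activation, 1 and 0 for cytotoxic and 2 and 0 for glycolysis genes. Without Dicer WT 2 they were 3 and 1 for activation, 3 and 1 for immediate early and 2 and 1 for glycolysis genes, and without Dicer KO 1 they were 2 and 1 for cytotoxic and 3 and 1 for glycolysis genes. Without Dicer KO 2 they were 0 and 0 for activation, 2 and 1 for immediate early, 1 and 0 for cytotoxic and 1 and 0 for glycolysis genes. Without Dicer KO 3 they were 2 and 0 for Th17, 4 and 0 for cytotoxic and 2 and 1 for glycolysis genes.

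Among markers of further cell types, macrophage and monocyte genes had 3 of 19 members higher, the protease Ctss (0.66 ± 0.05), Lyz2 (0.69 ± 0.12) and Cd163 (0.26 ± 0.05), and the list was not called by camera (adjusted p = 0.126) but was by fry (0.0362). Lyz2 lost its call without Dicer WT 1 or Dicer KO 2 (0.0654 and 0.0699), and Cd163 without any array but Dicer WT 2 (0.0663 to 0.105), so that 1 member was called without Dicer WT 1 or Dicer KO 2. Stromal and endothelial genes had 1 of 14 higher, Pecam1 (0.75 ± 0.07; adjusted p = 0.973). No member passed among 16 dendritic cell (adjusted p = 0.973), 15 natural killer and invariant NKT cell (0.896), 6 gamma delta T cell (0.546), 9 plasma cell (0.432), 14 neutrophil (0.69), 5 erythroid (0.432), 6 platelet (0.546) and 5 sex-linked genes (0.69). Adjusted over the list alone, 1 erythroid gene, Car2 (-0.22 ± 0.06), was lower and the other counts did not change. Median, mean and camera direction differed in sign for the activation, follicular helper, dendritic cell and stromal lists.

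**Figure D3:**
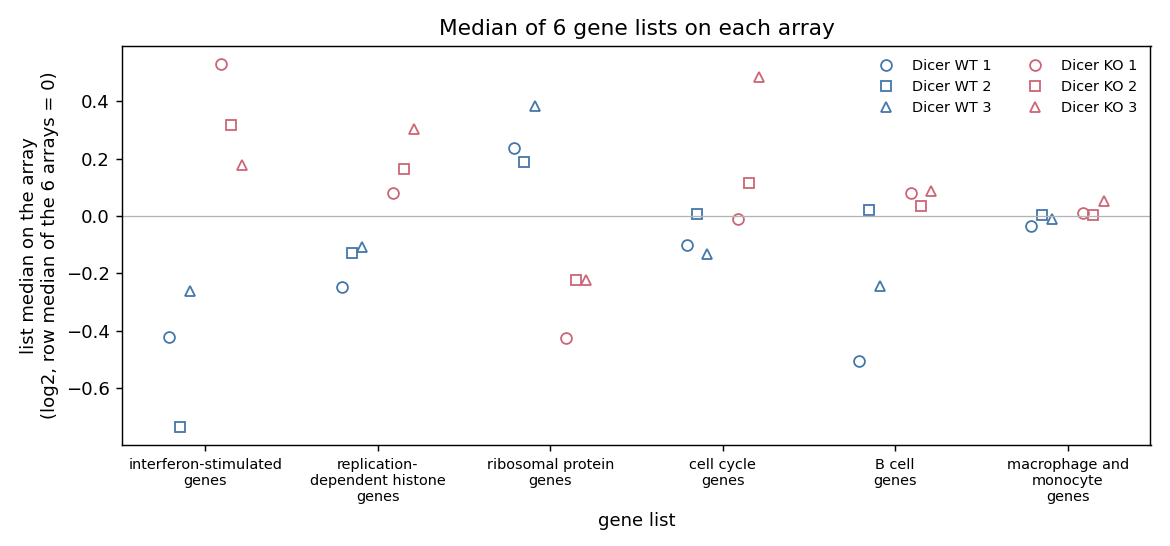
Median of each of 6 gene lists on each array (y axis, log2 with the row median of the 6 arrays at 0), with Dicer WT in blue, Dicer KO in red and a symbol per replicate number. Interferon-stimulated, histone, ribosomal protein and B cell genes separate the genotypes on all arrays. For B cell genes the gap is narrow, from 0.02 on Dicer WT 2 to 0.04 on Dicer KO 2, and their median is lowest on Dicer WT 1 at -0.51. The cell cycle median is highest on Dicer KO 3 at 0.48.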

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

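All tests of explanations in this part were chosen only after the result was seen, except the one of ribosomal rows shared with pseudogenes. The intervals of these tests resample genes as if independent and hold the arrays fixed. They leave out variation between arrays and are therefore too narrow. The correlation between genes was estimated at 0.54 for the interferon list and 0.75 for the B cell list. What the intervals are used to weigh holds for these arrays only.

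Rows of the array outside the gene-level comparison also differed between genotypes. When every row was tested with limma, 335 of the 5430 rows unnamed here (111 higher and 224 lower in Dicer KO) and 313 of the 1605 rows with several genes (83 higher and 230 lower) passed adjusted p 0.05. They stand outside the comparison because they name no gene or more than 1.

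Interferon-stimulated genes were higher in Dicer KO, with a list median of 0.77 and a lower value on each Dicer WT array than on each Dicer KO array. The B cell list median was also lower on each Dicer WT array than on each Dicer KO array. B cells in the KO sorts would raise their own markers at least as much. The interferon median exceeded the median of 18 B cell genes by 0.46 (bootstrap 95% interval over genes 0.16 to 0.81). Without Dicer WT 2, it did so only by 0.22 (-0.14 to 0.42). That leaves Dicer WT 1 and Dicer WT 3, the arrays of low B cell markers, as the WT arrays. Cd74, such a marker chosen after its value was seen, had a KO minus WT difference of 0.74 ± 0.26 SE. It was not called (limma adjusted p = 0.15) but was called without Dicer WT 2 (0.0494). Without Dicer WT 1 and Dicer WT 3 the excess was 0.92, which cannot weigh B cells. Leaving out arrays for low B cell markers brings the B cell median near 0 (0.03). The lone WT array left, Dicer WT 2, has the lowest interferon median (-0.74). For macrophages or dendritic cells in the KO sorts, the median of their 34 genes was 0.00786 (interval -0.029 to 0.05), below the limit of 0.15 set from the interferon median, but only 3 of the 34 are of the higher level class and 3 passed as higher, Ctss (0.66 ± 0.05), Lyz2 (0.69 ± 0.12) and Cd163 (0.26 ± 0.05), so these cells cannot be told apart from a change in the T cells. Of 10000 random lists of the same size and level classes, 0 reached the interferon median, which argues against a shift between the level classes as the source. Only 9 of the 33 interferon genes were of the higher class, and a trend with level within a class was not tested. An effect of the genotype on interferon signalling remains a hypothesis, and a difference in infection or housing between the animals is open and untested.

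Ribosomal protein genes were lower, with a list median of -0.54. Compression or scaling shared by bright transcripts on the KO arrays is not what 32 other abundant T cell transcripts showed as a set. Their median was 0.20 (interval 0.03 to 0.28), against a limit of -0.27 set from the ribosomal median. This list was not neutral: it held the ribosomal protein gene Fau (-0.58) and the interferon-inducible genes Ly6e (1.01) and B2m (0.61). Of its members, 9 were called higher and 4 lower, the lower ones being Ftl1 (-0.67), Npm1 (-0.53), Tpt1 (-0.35) and Fau. The deposited values hold no levels, so whether these transcripts were as bright as the ribosomal ones is unknown. Compression of the brightest rows alone is therefore left open. Loss of short mRNAs would lower others likewise, yet 45 of them, with 6 called lower, had a median of -0.18 (interval -0.24 to -0.11), and the 14 of the higher level class, which holds 49 of the 61 ribosomal genes, 0.021 (camera adjusted p = 0.00968 as lower than the rest of that class), which argues against it as the whole cause, while snoRNA genes, with a median of -0.33, went past the limit and leave a part open. Ribosomal protein genes with 1 row had a median of -0.55 (interval -0.68 to -0.40), as low as those with several rows (-0.54). The number of rows does not show whether probes match pseudogenes, so this comparison cannot decide on pseudogenes as the source. Lower ribosomal protein expression in Dicer KO cells stays open as a hypothesis.

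Histone genes were higher, and a larger share of cycling cells on the KO arrays is a candidate explanation. Without Dicer KO 3, the array with the highest cell cycle median, the histone median was 0.25 and the cell cycle median 0.15, a difference of 0.10 (bootstrap 95% interval -0.05 to 0.29). That interval covers 0, so cycling and a change of histone transcripts apart from cycling cannot be told apart with these lists.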

How the results depend on the processing

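Of 109 called genes named by the rule, 31 kept direction and call under every alternative that tested them singly and 0 reversed. The minimum log2 difference of 1 and the fit of all rows were compared by total counts only. With any 1 array left out, 69 kept the call. The counts of genes called, higher and lower were 1741, 1184 and 557. They ranged from 729 to 1597, 553 to 1070 and 176 to 527 with 1 array left out, fewer arrays giving less power. Alternatives set before the data were examined gave 103, 93 and 10 with a log2 difference of at least 1, 2685 and 1188 (called and lower) over all rows, and 897 lower genes with array weights. Among alternatives chosen after seeing the data, genes of level 8 or more gave 1010 called and 176 lower, and leaving out both arrays of low B cell markers gave 213, 192 and 21. That fit has a lone WT sample, assumed to vary like the others. The cause of the changes with array weights was not tested. Lists called numbered 17, 8 among genes of level 8 or more, where 16 lists could be tested, and 0 with an estimated correlation. Fry called 16, without the cell cycle (0.324), oxidative phosphorylation (0.462) and B cell lists (0.178) and with the macrophage (0.0362) and cytotoxic lists (0.0452). Dicer1 (0.02) reversed to -0.029 with array weights and -0.082 with level class centring, and ran from -0.069 to 0.080 with 1 array left out; the cause was not tested.

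Pairing of arrays by replicate number was not settled. Correlations of deviations between arrays of the same number were 0.27, -0.08 and 0.30 for numbers 1 to 3. Of 6 arrays, 4 correlated best with their own number, so a batch shared within a number is not excluded. With the replicate block, 2063 genes were called, 1407 higher and 656 lower, and 2 of the called genes named by the rule lost their call. Other reversals, cause not tested, were Fcer1g (0.016), Slc4a1 (-0.026), Ptcra (-0.050) and the lists of follicular helper (adjusted p 0.883), natural killer (0.846) and stromal genes (0.953) without both arrays of low B cell markers; natural killer and stromal genes (both 0.967) with array weights; host transcripts (0.731), activation genes (0.536), thymic emigrant genes and abundant transcripts (both 0.851) among genes of level 8 or more; and dendritic cell genes (0.976) with fry. Abundant transcripts were called with all genes (0.00348), the others were not called. With 1 array left out, reversals, cause not tested, widened the ranges of Slc4a1 (-0.0011 to 0.047), Gp5 (-0.060 to 0.0037), Kdm5d (-0.072 to 0.0063), Xist (-0.27 to 0.017), Cd8a (-0.27 to 0.10) and Ptcra (-0.020 to 0.084), and the adjusted p ran from 0.713 to 0.984 for follicular helper, 0.702 to 0.977 for natural killer, 0.28 to 0.936 for gamma delta, 0.644 to 0.956 for dendritic cell, 0.481 to 0.956 for neutrophil and 0.795 to 0.977 for stromal genes. Quantile normalization, percentile filters, another pseudocount, the trended prior and the seed site alternatives were not run: the table holds no levels, and no sequences were used. No filter and the mean of rows became the analysis itself. How far signal lay above background is unknown for the same reason.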

Other observations

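The gene lists of this part were written after the data had been looked at. Their members named here were chosen after their values were seen. The adjusted p of such a list covers the lists of this part alone. It describes the list and is not evidence of a genotype difference, because the list was tested on data already looked at. Of the tests below, the count of genes over splits was chosen only after the result was seen. The test of thymic emigrants and the count of lists over splits were written before they were run.

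Genes that load and present peptides on MHC class I were higher in Dicer KO. Of 16 members, 14 rose and 0 fell, with a median of 0.69, or 1.61-fold (camera adjusted p = 1.63e-17; adjusted p = 0.0675 with an estimated correlation). Examples are the peptide transporter Tap1 (0.82 ± 0.08 SE), tapasin, Tapbp (0.84 ± 0.10), its relative Tapbpl (1.02 ± 0.10) and the disulfide isomerase Pdia3 (0.84 ± 0.05). B2m, the light chain of MHC class I molecules, was 1.52-fold higher (0.61 ± 0.07). Interferon-inducible GTPases, which act on vacuoles of intracellular pathogens and were listed after their values were seen, so that no list test is given, had 9 of 10 members higher and 0 lower, with a median of 1.44, among them Gbp5 (1.55 ± 0.14), Gbp7 (1.69 ± 0.20) and Irgm1 (1.48 ± 0.16). Gbp3, Iigp1 and Irgm1 are also on the fixed interferon list, so the GTPase counts are not separate from the rise of that list. The signalling inhibitor Socs3 was 1.83-fold higher (0.87 ± 0.07).

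Genes of cholesterol synthesis were lower in Dicer KO. Of 19 members, 9 fell and 0 rose, with a median of -0.31 (camera adjusted p = 1.27e-10; adjusted p = 0.0831 with an estimated correlation). They included the transcription factor Srebf2 (-0.54 ± 0.05), squalene epoxidase, Sqle (-0.86 ± 0.10), Fdps (-0.61 ± 0.09) and Cyp51 (-0.48 ± 0.06). The members lower numbered 4 without Dicer WT 1, Dicer WT 2 or Dicer KO 2. Small nucleolar RNA genes, many of which lie in introns of ribosomal protein and translation factor genes, also went down, with 15 of 51 lower, 0 higher and a median of -0.33 (adjusted p = 3.2e-11; adjusted p = 0.0831 with an estimated correlation). Snora7a (-0.51 ± 0.06), Snora44 (-0.54 ± 0.07) and Snord49b (-0.68 ± 0.10) were examples, and 9 members fell without Dicer WT 1. Of 26 translation initiation and elongation factors, 3 rose and 3 fell, Eef1b2 by -0.91 ± 0.12, and without Dicer KO 2 the counts were 2 and 1. The list was not called (camera adjusted p = 0.425). It was called lower among genes of the higher level class (0.00968) and after centring within level classes (0.0195). Other abundant T cell transcripts, which include the ribosomal protein gene Fau, had 9 of 32 higher and 4 lower (camera adjusted p = 0.00348). Their adjusted p was 0.0831 with an estimated correlation and 0.376 after centring within level classes. Among genes of the higher level class it was 0.851, turned lower. Other short mRNAs had 1 of 45 higher and 6 lower (camera adjusted p = 1.92e-05). Their adjusted p was 0.257 with an estimated correlation and 0.0761 with fry. Without Dicer KO 2 the counts higher and lower were 5 and 1 for the abundant and 0 and 1 for the short transcripts; without Dicer WT 1, 2 abundant transcripts were lower, and without Dicer WT 2, 3 short ones.

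The rise of Dntt, with Ccr9 at 1.18 ± 0.20 (adjusted p = 0.015, but 0.0611 without Dicer WT 1), raised the hypothesis that recent thymic emigrants may be more frequent in the Dicer KO sorts. The other 23 genes of thymocytes and recent emigrants had a median of 0.04, 3 higher and 1 lower, with camera p = 0.425 (adjusted p = 0.602 with an estimated correlation). With 1 array left out, the median ran from -0.0077 (without Dicer WT 3) to 0.082 (without Dicer WT 1). The counts higher and lower were 0 and 1 without Dicer WT 1, 0 and 2 without Dicer KO 1, and 0 and 1 without Dicer KO 2. Rag1 (-0.06 ± 0.06, adjusted p = 0.673) and Ptcra (0.04 ± 0.07, adjusted p = 0.829), which are expressed at earlier thymic stages, did not pass. The rule written for this test had taken a p of 0.05 or more as evidence against, which was too strict: a missed p sets no bound, and genes shut off before cells leave the thymus would not show emigrants. The hypothesis stays open.

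Splits of the 6 arrays into 3 and 3 were too few, at 10, for a share under 0.05. The real split called 1741 genes and the highest of the other 9 called 0 with limma, with up to 1520 genes at unadjusted p under 0.05 against 4285. It called 17 gene lists and the highest of the others 10. In each case 1 split, the real one, gave a count as large. All other splits called at least 4 lists. Each of them keeps a part of any genotype difference, and that part was not separated from variation shared between arrays.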
